A study of Mus musculus with 68 samples.

How the data were processed

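The series measured RNA of mouse lung on 1-colour Agilent arrays, with 68 arrays of 62976 features each. Alveolar septa and vessel compartment were taken by laser microdissection. Per the labels, RNA was purified with a Qiagen RNeasy Micro kit, amplified with the NuGEN Ovation PicoSL WTA System V2 and labelled with Cy3 by the SureTag kit. The values deposited by the authors are log2 intensities, and their notes name limma without a version. The deposited log2 values ran from 3.27 to 15.98. At each percentile the arrays differed by at most 0.00352, so the values were already quantile normalised over all arrays. The background correction used by the authors is not given in the sources used here, and no flags for dim spots came with the values. For arrays, the number of arrays limits the precision; no depth applies.

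Groups were taken from the sample titles and gave 14 groups of 4 or 5 arrays, with 7 groups and 34 arrays in each compartment. The fourth wild-type smoke septa array carries a knock-down entry among its characteristics, against its title; the title was used, and the entry was tried as an alternative. The replicate numbers were not used as pairs. The treatment text also names animals with a reduced Fgfr2b dose, but no sample is labelled so.

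Features were named by the platform annotation and a RefSeq table of the mouse, which left 43941 features with 1 gene name and 24583 gene names. Genome coordinates were not analysed here. Each gene was represented by its brightest probe. A gene was tested if it lay above the array's percentile 40 on at least 4 arrays. Genes with any of the 44 missing values, which lay on 5 arrays, were left out (5 genes in septa and 10 in vessel). This left 21752 genes in septa, 22517 in vessel and 24150 for both compartments together.

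Each compartment was fitted with limma 3.58.1 in R 4.3.3, as a model of 7 group means with moderated variances, and 8 comparisons were drawn from it. The comparison of septa with vessel, and the differences of effects between compartments, came from a fit of all 14 groups. All tests were two-sided. The groups of a fit share 1 estimate of the spread per gene, so each array enters the spread of every comparison. At limma unadjusted p under 0.05, chance alone gives about 1087.6 genes in septa, 1125.85 in vessel and 1207.5 for both compartments together. A count under these numbers does not show that an effect is absent. Adjusted p values are Benjamini-Hochberg values over the genes of a comparison, with a threshold of 0.05. Simulated data with 50 genes changed at each of 1, 2, 3 and 4 log2 units were tested in the wild-type smoke comparison. Each gene had the spread pooled over all 7 groups of its compartment, the arrays of low correlation named below included. The mean pooled variance was 1.51 in septa and 1.50 in vessel. In wild-type room air it was 1.06 and 2.30, so the recovery does not carry over to groups of another spread. The fit recovered 2 percent of genes changed by 1 log2 unit in septa and 0 percent in vessel. For 2 log2 units the fit recovered 14 percent in septa and 32 percent in vessel. At 4 log2 units it recovered 86 percent in septa and 82 percent in vessel.

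A set of 45 gene lists was fixed before the data were examined, together with the grouping, the filter, the comparisons, the alternatives named next as fixed and the rule for naming genes. By that rule, the 10 genes with the largest rise and the 10 with the largest fall past the threshold are open to naming, without predicted or clone-named genes. Members of the lists past the threshold are open to naming as examples. Where fewer than 5 genes pass, the 5 with the smallest p are open to naming as not having passed. Fgf10, Fgfr2, Etv4, Etv5, Dusp6, Spry2, Spry4 and Nos2 were followed in each comparison. Lists were tested with camera at a preset correlation of 0.01, beside camera with an estimated correlation, both adjusted over the 45 lists of a comparison. The fry test was run beside them. It asks whether a list moves one way on balance, without comparing it with other genes.

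The alternatives fixed at that time were no filter, the mean of all probes of a gene, each array centred on its median, array weights, fits of the compared groups alone, a replicate block, the conflicting sample counted as knock-down, and each array left out in turn. Quantile normalisation had been planned as an alternative and was void, since the values were already quantile normalised; centring took its place. Chosen after seeing the data were a fit without the 3 arrays whose median correlation with their compartment was under 0.6, a covariate for Xist signal over 9.5, and both together. Genes that pass only without the low-correlation arrays are named in the report by the same rule, and so were chosen after the data were seen.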

Results

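The arrays measured RNA in laser-microdissected alveolar septa and vessels of mouse lungs, with 34 arrays per compartment. After 3 months of room air or cigarette smoke there were 5 wild-type room air, 5 wild-type smoke, 4 Fgf10 knock-down room air and 5 Fgf10 knock-down smoke arrays in each compartment. After 8 months, followed by 1 week with or without doxycycline, there were 5 room air controls, 5 smoke controls and 5 smoke arrays labelled Fgf10 overexpression. Fgf10 is a growth factor of lung mesenchyme that signals to epithelium through Fgfr2b. The labels frame 3 questions: what smoke changes, what a lower Fgf10 dose changes with and without smoke, and what Fgf10 given after smoke changes. Changes are log2 fold changes with their standard error (SE). Changes are differences of group means as fitted, without subtracting the median of all genes, which moved by over 0.1 only in comparisons with the knock-down smoke arrays. That median was -0.15 for knock-down against wild type under smoke in septa, -0.20 for smoke in the knock-down in septa and -0.22 for their interaction. In vessel the same medians were -0.10, -0.12 and -0.22. A change set against a mean under the percentile of 40 of the arrays, about 5.32, or against readings near the highest value deposited, has no exact size.

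Surfactant protein C (Sftpc) read 15.17 or more on every array except knock-down smoke septa replicate 5, where it read 4.59. That array had a median correlation of -0.0176 with the other septa arrays, and knock-down smoke septa replicate 1 had 0.243. The lowest array in vessel was knock-down smoke replicate 5, at 0.456. Medians of the other arrays lay at 0.691 or more. These 3 arrays are called the low-correlation arrays below, and each comparison was also run without them, a step chosen after seeing the data. Arrays with high Xist signal, the RNA of the inactive X chromosome, were 3 of 5 in the knock-down smoke group and 1 of 5 in the wild-type smoke group. The counts per group were alike in septa and vessel, and sex is not given in the labels.

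**Figure D1:**
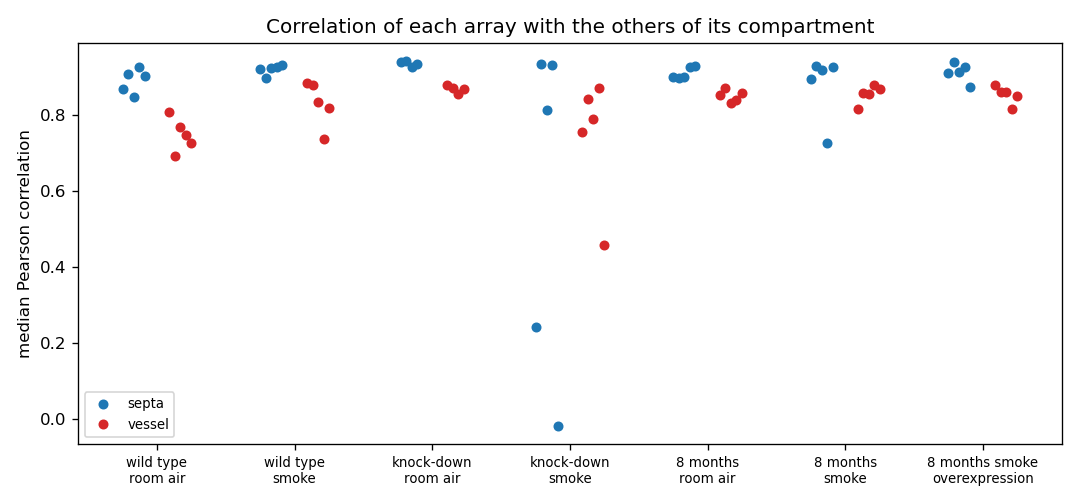
Median Pearson correlation of each array with the other arrays of its compartment, by group, with 1 point per array and compartments in separate colours. Knock-down smoke septa replicates 5 (-0.0176) and 1 (0.243) and knock-down smoke vessel replicate 5 (0.456) lie below 0.6.

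In septa Fgf10 signal at the brightest probe was not lower on room air arrays labelled knock-down. There it read 7.71 ± 0.58 (SD, n = 5) in wild-type room air and 8.36 ± 0.60 (SD, n = 4) in the group labelled knock-down, a change of 0.65 ± 0.78 (SE; limma adjusted p = 1). In vessel the change was 0.26 ± 0.98 (SE, n = 4 against 5; limma adjusted p = 0.923), but the probe lay above the percentile of 40 on 1 of 4 knock-down and 1 of 5 wild-type arrays, so it could hardly read lower. A dimmer probe changed by -0.39 in septa and -0.98 in vessel in room air (limma unadjusted p = 0.69 and 0.273). In vessel that probe lay above the percentile of 40 on 0 of 4 knock-down and 1 of 5 wild-type arrays. Under smoke in septa Fgf10 at the brightest probe read 5.82 ± 2.21 (SD, n = 5) in the group labelled knock-down and 8.50 ± 1.29 (SD, n = 5) in wild type. It fell by 2.68 ± 0.74 (SE; limma adjusted p = 0.0498), but without the low-correlation arrays the change was -1.65 (limma adjusted p = 0.999). In the same comparison, with all arrays, that dimmer probe changed by 1.34 (limma unadjusted p = 0.15). The dimmest lay at background, above the percentile of 40 on 1 of 5 knock-down and 0 of 5 wild-type arrays. In vessel under smoke the change of Fgf10 was -0.75 ± 0.92 (SE, n = 5 per group; limma adjusted p = 0.706). Arrays labelled overexpression read 8.21 ± 0.91 in septa and 5.47 ± 1.60 in vessel, against 9.01 ± 1.11 and 7.31 ± 1.08 in smoke controls (SD, n = 5 each). That dimmer Fgf10 probe read 7.59 ± 1.76 in septa and 7.84 ± 2.13 in vessel on overexpression arrays (SD, n = 5 each). Room air controls read 5.42 ± 0.72 and 4.45 ± 0.62 on it (SD, n = 5 each). These differences of 2.17 and 3.39 had exact two-sided permutation p of 0.0159 and 0.0317, each 0.0635 when adjusted over 4 tests. Limma, with the spread shared by all groups, gave unadjusted p of 0.0234 in septa and 0.000277 in vessel. Room air controls differ by smoke as well, and against smoke controls the differences on this probe were 1.58 and 2.22 (exact two-sided permutation p of 0.151 and 0.119, each 0.151 when adjusted). Limma gave unadjusted p of 0.0926 in septa and 0.0116 in vessel against smoke controls. In vessel the room air controls lay above the percentile of 40 on 1 of 5 arrays, so 3.39 is set against a level near background. Whether any probe lies in the altered part of the gene or in the transgene is not given in the sources used here. The direction of each Fgf10 comparison below therefore rests on the labels.

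**Figure D2:**
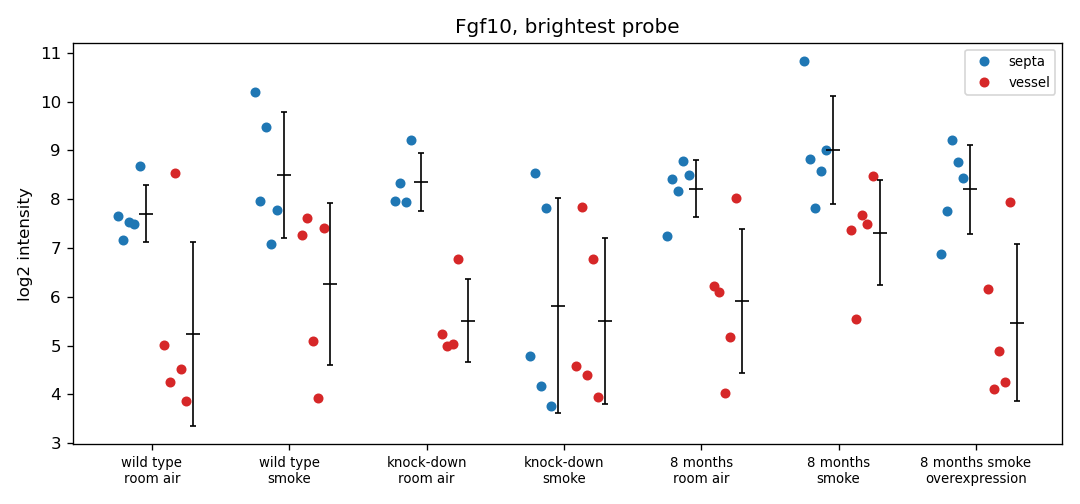
Fgf10 log2 signal at the brightest probe on each array, by group, with the mean and standard deviation beside the points of each group and septa and vessel in separate colours. Septa group means run from 5.82 in knock-down smoke to 9.01 in smoke controls of 8 months.

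The receptor Fgfr2, the transcription factors Etv4 and Etv5, and the feedback inhibitors Dusp6, Spry2 and Spry4 did not pass the test in any of the 8 comparisons of either compartment. Nos2, the inducible nitric oxide synthase, did not pass either. Closest by adjusted p were Spry2, at -2.44 ± 0.79 (SE, limma adjusted p = 0.0591), and Dusp6, at -2.49 ± 0.85 (SE, limma adjusted p = 0.0673), on the arrays labelled knock-down under smoke in septa (n = 5 per group). With the low-correlation arrays left out these were -0.28 and -0.30 (limma adjusted p = 0.999 for each). By unadjusted p Spry4 stood lower, at 2.15 after 8 months of smoke in septa (limma unadjusted p = 0.00256). Spry2 and Dusp6 had limma unadjusted p of 0.00425 and 0.00703, all from a fit of the probes of the followed genes. Other members of the FGF list passed under smoke. In septa Dusp4 was at -4.14 ± 0.93 (SE, limma adjusted p = 0.0493; 1 of 2 probes in that direction) and Spry1 at -2.80 ± 0.81 (SE, limma adjusted p = 0.0498) on the arrays labelled knock-down, and at -2.87 and -0.47 with the low-correlation arrays left out (limma adjusted p = 0.999 for each). In vessel Spred3 was at -1.87 ± 0.53 (SE, limma adjusted p = 0.0361), and at -2.18 without the low-correlation array (limma adjusted p = 0.0162). Bmp4 was at 1.82 ± 0.53 (SE, limma adjusted p = 0.0388) and Fgfr3 at 1.53 ± 0.45 (SE, limma adjusted p = 0.0403) in vessel, with adjusted p of 0.053 and 0.0766 (limma) without that array. Nos2 was -0.92 ± 0.81 in septa and -0.05 ± 0.40 in vessel (SE, n = 5 per group) for 3 months of smoke in wild type. After 8 months of smoke Nos2 was -0.20 ± 0.81 in septa and 0.32 ± 0.40 in vessel.

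Septa and vessel differed first in the contractile and matrix genes of the vessel wall. Actc1, cardiac actin, was lower in septa by a log2 difference of -6.87 ± 0.24 (SE, 34 arrays per compartment; limma adjusted p = 2.08e-33). Cnn1, smooth muscle calponin, differed by -6.14 ± 0.21 (SE, limma adjusted p = 2.03e-33). Sfrp2, a secreted Wnt modulator of fibroblasts, differed by -6.99 ± 0.42, Dcn, the collagen-binding proteoglycan decorin, by -5.61 ± 0.30, and Gpc6 by -5.31 ± 0.33. Acta1, Actg2, Mustn1, Sulf1 and Cyp2s1 lay between -4.69 and -4.46. Higher in septa were Dcbld1 at 3.49 ± 0.41, the sulfate transporter Slc13a4 at 3.30 ± 0.41 and Gzma, a granzyme of cytotoxic lymphocytes, at 3.29 ± 0.45. Bmper, a regulator of BMP signals, stood at 3.17 ± 0.39 and Slco2a1, a prostaglandin transporter, at 3.03 ± 0.44. Fgf10 itself was higher in septa, by 2.09 ± 0.32 (SE, limma adjusted p = 1.35e-06), as was Etv5, by 1.26 ± 0.18. Nos2 was lower, at -1.46 ± 0.25.

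By cell type, 15 of 21 vascular smooth muscle genes were lower in septa (15 adjusted over the list alone), among them Myh11 at -3.96 ± 0.22 and Myl9 at -4.20 ± 0.20. Camera gave this list an adjusted p of 3.45e-31, and an adjusted p of 5.45e-08 with an estimated correlation. Pulmonary vein cardiomyocyte genes were lower for 17 of 22 (18 adjusted over the list alone; camera adjusted p = 2.98e-15, and adjusted p = 0.0292 with an estimated correlation). Examples were Myl7 at -3.77 ± 0.63 and Tnnt2 at -3.65 ± 0.53. Adventitial fibroblast genes were lower for 14 of 20 (15 adjusted over the list alone; camera adjusted p = 4.32e-19, and adjusted p = 6.27e-07 with an estimated correlation). Airway club and ciliated cell genes were lower for 7 of 18 and higher for 1 (8 and 1 adjusted over the list alone), with Scgb3a2 at -3.11 ± 0.37 and Cyp2f2 at -3.19 ± 0.35. That list had a camera adjusted p of 3.88e-06, and an adjusted p of 0.00377 with an estimated correlation. Elastic fibre genes were lower for 9 of 18 and higher for 1, the same when adjusted over the list alone (camera adjusted p = 3.03e-06, and adjusted p = 0.0292 with an estimated correlation). Skeletal muscle genes, many of them shared with other muscle, were lower for 7 of 15 and higher for 1 (8 and 1 adjusted over the list alone). Their camera adjusted p was 0.000575, and the adjusted p was 0.0292 with an estimated correlation.

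Capillary endothelial genes were higher in septa for 14 of 20 (15 adjusted over the list alone; camera adjusted p = 3.55e-12, and adjusted p = 0.0395 with an estimated correlation). Alveolar type 1 cell genes were higher for 12 of 18 (13 adjusted over the list alone), with camera adjusted p = 5.22e-07 but adjusted p = 0.158 with an estimated correlation. Neutrophil genes were higher for 12 of 20 (13 adjusted over the list alone; camera adjusted p = 1.1e-07, but adjusted p = 0.0519 with an estimated correlation). The list of FGF10 signalling and its targets had 10 of 26 genes higher and 3 lower, the same when adjusted over the list alone (camera adjusted p = 0.013, but adjusted p = 0.196 with an estimated correlation). Across both directions 2645 genes were higher and 2137 lower in septa, of 24150. With the low-correlation arrays left out 4329 were higher and 3506 lower, 4672 of them shared with the fit of all arrays, and in wild-type room air arrays alone 460 passed.

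Smoke for 3 months in wild-type septa raised Slco2b1, a transporter of organic anions, by 3.83 ± 0.68 (SE, n = 5 per group; limma adjusted p = 0.0429), with 5 of 5 smoke arrays above the room air mean. It was the only gene of 21752 to pass. No gene passed with centred arrays, with the mean of all probes or with the array of conflicting labels counted as knock-down (limma; 0 each, 806, 881 and 727 at unadjusted p under 0.05), and in a fit of these groups alone 4 others did. Cxcl5, a neutrophil-attracting chemokine, read 10.90 ± 1.60 under smoke and 5.21 ± 0.99 in room air (SD, n = 5 each; limma adjusted p = 0.0524). Marco, a scavenger receptor of macrophages, was at 3.64 ± 0.75 (SE, limma adjusted p = 0.164). Nme7 was at 4.37 ± 0.98 and Dbp, a clock-controlled transcription factor, at 3.99 ± 0.91 (SE, limma adjusted p = 0.369 each). Without the low-correlation arrays, none of which belongs to these groups, 9 genes rose and 2 fell. Those arrays enter only the shared spread. With all arrays 765 genes had limma unadjusted p under 0.05, and 2169 without them. Cxcl5 (limma adjusted p = 0.00483), Marco (0.0314), Dbp (0.0433), the clock gene Per3 (0.0433), the epithelial protein Plet1 (0.0314) and Gpnmb, a lysosomal protein of lipid-laden macrophages (0.0272), were then among those that rose. Rprl2 and the sodium channel Scn9a then fell, at -3.16 and -2.02. The room air means of Cxcl5, Nme7 and Gpnmb and the smoke mean of Scn9a lay under the percentile of 40.

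Macrophage lists lay higher in these septa as groups. Of 20 alveolar macrophage genes 17 had a positive change, with a median of 1.22, and 0 passed the limma test over all genes (6 adjusted over the list alone). Camera gave an adjusted p of 3.42e-09, but an adjusted p of 0.201 with an estimated correlation. Smoke-exposed and lipid-loaded macrophage genes had a median of 0.91, with 6 passing when adjusted over the list alone (camera adjusted p = 3.42e-09, but adjusted p = 0.336 with an estimated correlation). Inflammatory cytokines had a median of 0.55 (camera adjusted p = 0.000473, but adjusted p = 0.172 with an estimated correlation). The B cell, plasma cell and lymphoid follicle list moved down, with a median of -1.02 and 5 of 19 genes lower when adjusted over the list alone. Its camera adjusted p was 3.42e-09, and its adjusted p was 0.0174 with an estimated correlation. The count of 1 gene fell to 0 without wild-type smoke replicate 1 and was 2 without wild-type room air replicate 1.

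In wild-type vessel, 3 months of smoke raised 23 genes and lowered 9 of 22517. Per3 rose from 5.77 ± 0.96 to 11.65 ± 1.55 (SD, n = 5 each; limma adjusted p = 0.00676), above the room air mean on 5 of 5 smoke arrays. Means of the circadian clock list ran from 7.72 to 8.06 on wild-type room air vessel arrays and from 7.96 to 9.59 under smoke. On room air vessel arrays labelled knock-down they ran from 8.70 to 9.48. Low wild-type room air readings thus enter clock changes in this comparison, and smoke cannot be told apart from them. Cxcl5 rose by 5.57 ± 1.17, the cholesterol exporter Abca1 by 5.19 ± 0.96, the motor protein Myo5a by 4.44 ± 0.91 and Cfb, complement factor B, by 4.42 ± 0.90 (SE, n = 5 per group; limma adjusted p from 0.0286 to 0.0405). Spopl, an adaptor of ubiquitin ligases, rose by 5.38 ± 0.79, with only 1 of its 4 probes in that direction. Alg2, of protein glycosylation, rose by 5.49 ± 1.19, with 1 of 2 probes in that direction. The transporter Abcc3 and the kinase Cdk12 each rose by 4.08, and the noncoding RNA Oip5os1 by 3.83 ± 0.81. Among list members, the mannose receptor Mrc1 rose by 3.43 ± 0.70, the mitochondrial superoxide dismutase Sod2 by 3.35 ± 0.71 and the chemokine Ccl6 by 3.15 ± 0.66 (limma adjusted p = 0.0405 each). Among genes that fell, Med21, a Mediator subunit, was at -3.14 ± 0.56, Gldn at -2.79 ± 0.56 and Il1rapl2 at -2.56 ± 0.55. The odorant receptors Olfr49 and Olfr683 were at -2.68 ± 0.55 and -2.15 ± 0.45. The means of Cxcl5 and Mrc1 in room air, and of Gldn, Il1rapl2, Olfr49 and Olfr683 under smoke, lay under the percentile of 40.

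As groups in this comparison, smoke-exposed macrophage genes had a median of 1.13 with 5 of 20 passing when adjusted over the list alone (camera adjusted p = 1.55e-05, but adjusted p = 0.318 with an estimated correlation). Inflammatory cytokines had 2 of 29 genes up (3 adjusted over the list alone; camera adjusted p = 0.000199, but adjusted p = 0.318 with an estimated correlation). Cell cycle genes had a median of 0.89, with 6 of 24 up when adjusted over the list alone (camera adjusted p = 0.00158, but adjusted p = 0.318 with an estimated correlation). The T and NK cell list had a median of 0.78 (camera adjusted p = 0.0207, but adjusted p = 0.318 with an estimated correlation). The 32 calls became 135 without the low-correlation array (32 shared), 2 without wild-type smoke replicate 2, 264 without wild-type room air replicate 5, 1 with the mean of all probes and 0 in a fit of these 2 groups alone. In room air the vessel arrays of wild type had medians of correlation from 0.691 to 0.805, below most of their compartment.

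The arrays labelled knock-down in room air showed no gene past the threshold in septa (limma; 0 of 21752, 497 at unadjusted p under 0.05). Chance alone gives about 1087.6 at that level. The smallest p values belonged to Gm15708 at 2.94 ± 0.66, the stromelysin Mmp3 at 3.19 ± 0.76, Scn9a at -2.11 ± 0.52, Slco2b1 at 2.89 ± 0.72 and Dbp at 3.79 ± 0.96 (SE, n = 4 against 5; limma adjusted p = 1 each). The wild-type means of Gm15708 and Mmp3 and the knock-down mean of Scn9a lay under the percentile of 40. The low-correlation arrays lie in another group and enter only the shared spread. Without them 0 genes passed (limma, 1455 at unadjusted p under 0.05). With array weights 23 genes passed in this comparison, 11 higher and 12 lower. Circadian clock genes had 15 of 17 positive changes and a median of 1.07, with 2 up when adjusted over the list alone (camera adjusted p = 2.47e-05, but adjusted p = 0.0571 with an estimated correlation). Airway club and ciliated genes had 16 of 17 positive changes and a median of 0.73 (camera adjusted p = 0.0147, but adjusted p = 0.0571 with an estimated correlation).

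In vessel the arrays labelled knock-down in room air had 51 genes higher and 21 lower. Spopl rose by 5.38 ± 0.83 (SE, n = 4 against 5; limma adjusted p = 0.0025), Plekhd1 by 4.91 ± 0.83 (1 of 2 probes in that direction), Kmt5b, a histone methyltransferase, by 5.18 ± 0.93 and Brd1, a chromatin reader, by 5.16 ± 0.95. The calcium-store channel Tmem38a, the transcription factor Lyl1, the phosphatase Ppm1h, the trafficking protein Vps33b, the ubiquitin ligase Ube3c and the mitochondrial ribosomal protein Mrpl44 rose by 4.83 to 5.54. All of these lay above the wild-type mean on 4 of 4 arrays. Among genes that fell, Hspb3, a small heat shock protein, was at -3.50 ± 0.79, Acsm1 at -3.38 ± 0.78, the RNA-processing protein Ptcd1 at -2.69 ± 0.62 and Xylt1, which starts proteoglycan chains, at -2.29 ± 0.49. St18, Prss54, Olfr49, Hsfy2, Elavl2 and Olfr683 lay between -2.74 and -2.21. Per3 rose by 4.55 ± 1.00, Mrc1 by 3.54 ± 0.74 and Sod2 by 3.39 ± 0.76. The wild-type means of Plekhd1, Tmem38a, Ppm1h, Vps33b and Mrc1, and the knock-down means of Hspb3, Acsm1, St18, Prss54, Olfr49, Hsfy2, Elavl2 and Olfr683, lay under the percentile of 40.

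Clock genes as a list had a median of 1.23 in this comparison, with 1 of 17 up (3 adjusted over the list alone; camera adjusted p = 0.00916, but adjusted p = 0.652 with an estimated correlation). Interferon-stimulated genes had a median of 1.03 and 2 of 23 up when adjusted over the list alone (camera adjusted p = 0.00816, but adjusted p = 0.652 with an estimated correlation). Of the 51 genes that rose, 17 also rose with smoke in wild-type vessel, in comparisons that use the same wild-type room air arrays and so are not independent. The count of 72 was 210 without the low-correlation array (72 shared), 4 without knock-down room air replicate 3 and 215 without wild-type room air replicate 1. In a fit of these groups alone 28 genes were higher and 0 lower, 11 of them shared with the 72. With the replicate block 32 passed, 30 of them shared.

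Under smoke in septa, 90 genes were higher and 538 lower on the arrays labelled knock-down, at limma adjusted p of 0.0493 or more. Igf2r, a receptor that carries lysosomal enzymes, was at -4.82 ± 1.00 and the cytoskeletal linker Epb41l5 at -4.48 ± 0.81 (SE, n = 5 per group; limma adjusted p = 0.0493 each). Fignl2, Epb41l2, Tle4, Fosl2, Eif4a2, Phldb2 and Rab1a lay between -5.03 and -4.49. Cdh5, the endothelial cadherin, was at -4.44 ± 1.27, Cxcl15, a lung epithelial chemokine, at -3.97 ± 1.11 and Cd74, the invariant chain, at -3.87 ± 1.08. Pld5 rose by 4.04 ± 1.07, Ccdc92 by 3.71 ± 0.99, Cubn, an endocytic receptor, by 3.44 ± 0.93, Rbmx2 by 3.41 ± 0.89 and Igll1, a surrogate light chain, by 3.30 ± 0.87. The wild-type means of Pld5, Cubn, Rbmx2 and Igll1 lay under the percentile of 40. Every call ended without the low-correlation arrays (limma; 0 genes, 1036 at unadjusted p under 0.05), where Igf2r stood at -2.21, Cdh5 at -0.32 and Cxcl15 at -0.42. The count was also 0 without knock-down smoke replicate 1, with no filter, with the mean of all probes, with centred arrays, with array weights and in a fit of these groups alone, and 5076 without knock-down smoke replicate 2. With all arrays it was 4134 with the Xist covariate, 628 of them shared, and 697 with the replicate block, 606 of them shared. In knock-down smoke septa only the low-correlation replicates 1 and 5 lacked high Xist signal, at 5.78 and 6.42. Within this group the covariate parts the same arrays, so 4134 cannot be read as an adjustment for sex. With the covariate and without these arrays 0 genes passed (limma, 1505 at unadjusted p under 0.05).

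Lists moved down broadly in the same comparison. Capillary endothelial genes had 20 of 20 negative changes, with 2 down (14 adjusted over the list alone; camera adjusted p = 1.95e-05, but adjusted p = 0.454 with an estimated correlation). Alveolar type 2 genes had a median of -2.24 with 1 of 19 down (14 adjusted over the list alone; camera adjusted p = 4.76e-05, but adjusted p = 0.454 with an estimated correlation). Oxidative phosphorylation genes had a median of -1.51, with 11 of 28 down when adjusted over the list alone (camera adjusted p = 3.51e-05, but adjusted p = 0.454 with an estimated correlation). Heat shock and immediate-early genes had a median of -2.09 and angiogenesis factors one of -1.39. Camera called 21 lists down and 1 up; 0 held with an estimated correlation (smallest adjusted p = 0.454), and camera called 0 of 45 lists without the low-correlation arrays.

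Smoke in septa on the arrays labelled knock-down changed no gene with all arrays (limma; 0 of 21752, 6124 at unadjusted p under 0.05). The count depended on the model: with the Xist covariate 787 genes were higher and 2538 lower, and with array weights 33 passed, while with the covariate and without the low-correlation arrays none did (limma; 0, 1381 at unadjusted p under 0.05). Within knock-down smoke septa that covariate parts the low-correlation arrays from the rest, so its counts cannot be read as an adjustment for sex. Marco was at 4.12 ± 0.79 (SE, n = 5 against 4), and Mpzl1, Tcf20 and Klhl13 were at -3.90, -3.90 and -2.59 (limma adjusted p = 0.0641 each). Without the low-correlation arrays Marco rose by 5.09 (limma adjusted p = 0.0121) and Mreg, a melanosome and lysosome regulator, by 2.55 (limma adjusted p = 0.0197). Alveolar macrophage genes then had a median of 1.20 (camera adjusted p = 5.03e-11, and adjusted p = 0.0337 with an estimated correlation), and smoke-exposed macrophage genes one of 1.01 (camera adjusted p = 2.35e-10, and adjusted p = 0.0337 with an estimated correlation). With all arrays these medians were -0.02 and -1.08, and camera called 15 lists down and 1 up, of which 0 held with an estimated correlation. Without the low-correlation arrays camera called 4 lists down and 4 up, of which 2 held. The interaction of smoke and knock-down in septa had no gene past the threshold (limma; 0, 4056 at unadjusted p under 0.05). Smad2 was at -7.45 ± 1.46, Gm15708 at -4.18 ± 0.91, Setd5 at -4.81 ± 1.07, Rprl2 at 4.72 ± 1.06 and Abca8b at -4.74 ± 1.08 (SE, limma adjusted p = 0.23 each). For the interaction camera called 20 lists down and 1 up, of which 0 held with an estimated correlation. Left-out arrays gave counts of 0 to 4864 for smoke in the knock-down (4864 without knock-down smoke replicate 4) and 0 to 556 for the interaction (556 without knock-down smoke replicate 2). The interaction count was 10 with the Xist covariate and 3 with array weights.

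In vessel under smoke, 367 genes were higher and 843 lower on the arrays labelled knock-down, 897 of which also passed without the low-correlation array. Hbb-b1, a beta-globin of red cells, rose by 5.62 ± 1.69 (SE, n = 5 per group; limma adjusted p = 0.0463), Slc5a6, a vitamin transporter, by 4.04 ± 0.75 and Ntng1 by 3.92 ± 0.74, with 2 of its 4 probes in that direction. Atpsckmt, Bbof1, Calml3, Cstdc4 and Exoc3 rose by 3.25 to 3.95, Reg3g, a secreted antibacterial lectin, by 3.31 ± 0.91 and C8a, of the complement membrane attack complex, by 3.30 ± 0.65. Among genes that fell, Lhfpl5 was at -3.98 ± 0.66 (SE, limma adjusted p = 0.00285), Rab3il1 at -3.91 ± 0.67, the synaptic vesicle protein Sv2b at -3.85 ± 0.70, Necab2 at -3.70 ± 0.69 and Olfm3 at -3.67 ± 0.65. Olfr1344, Ggn, Serpina4-ps1, Cd300ld3 and Rnd1 lay between -3.72 and -3.47. Sox10, a Schwann cell factor, was at -2.97 ± 0.52, the mitotic kinase Plk1 at -3.44 ± 0.75 and Mzb1, of antibody-secreting cells, at -3.13 ± 0.79. Csf3, the granulocyte growth factor, rose by 2.92 ± 0.52 and Ifit3, an interferon target, by 2.98 ± 0.91. The wild-type means of Slc5a6, Ntng1, Calml3, Cstdc4, Exoc3, Reg3g, C8a and Csf3, and the knock-down means of Olfr1344, Cd300ld3 and Sox10, lay under the percentile of 40.

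Erythrocyte genes were higher in this vessel comparison for 2 of 11, with a median of 2.26 (3 adjusted over the list alone; camera adjusted p = 0.00446, but adjusted p = 0.984 with an estimated correlation). Interferon-stimulated genes were higher for 2 of 23, with a median of 0.74 (3 adjusted over the list alone; camera adjusted p = 0.0111, but adjusted p = 0.984 with an estimated correlation). The 1210 calls became 308 without wild-type smoke replicate 4, 763 with centred arrays, 4406 with array weights and 0 in a fit of these groups alone.

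Smoke in vessel on the arrays labelled knock-down raised 40 genes and lowered 1. Ntng1 rose by 4.24 ± 0.79, the lens filament gene Bfsp1 by 3.59 ± 0.64, Defb36, a beta-defensin, by 3.59 ± 0.69, the channel subunit Kcng3 by 3.22 ± 0.56 and C8a by 3.22 ± 0.69 (SE, n = 5 against 4; limma adjusted p from 0.0166 to 0.0457). Trh, the thyrotropin-releasing hormone precursor, Mep1b, Spdye4b, Csf3 and Olfr747 rose by 2.86 to 3.19, and the histone gene H4c8 fell by 3.53 ± 0.77. Apart from H4c8, the room air means of all of these lay under the percentile of 40. Pulmonary vein cardiomyocyte genes had a median of -2.28, with 3 of 22 down when adjusted over the list alone (camera adjusted p = 5.71e-06, but adjusted p = 0.464 with an estimated correlation). Vascular smooth muscle genes had a median of -0.78 (camera adjusted p = 4.22e-05, but adjusted p = 0.464 with an estimated correlation), and BMP, TGF-beta and pulmonary hypertension genes one of -1.01 (camera adjusted p = 0.00536, but adjusted p = 0.464 with an estimated correlation). The 41 calls became 22 without the low-correlation array, 14 of them shared, 0 without knock-down room air replicate 1, 295 without knock-down smoke replicate 4 and 0 in a fit of these groups alone.

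The interaction in vessel, the smoke effect in the knock-down minus that in wild type, passed for 2 genes upward and 3 downward. Med21 was at 4.57 ± 0.81 and Spopl at -6.54 ± 1.15, after smoke changes in wild type of -3.14 and 5.38 (SE, n = 4 or 5 per group; limma adjusted p = 0.0197 each). In wild type only 1 of 4 probes of Spopl rose with smoke. Spopl was also 5.38 higher on knock-down than on wild-type room air arrays, so low wild-type room air readings enter its interaction. The median correlations of those arrays ran from 0.691 to 0.805. Cd300ld3, a myeloid surface receptor, was at -5.72 ± 1.03, and Plk4, the centriole kinase, at -4.70 ± 0.82 with 1 of 4 probes in that direction. The remaining gene has a predicted name and was not open to naming. The count was 0 without knock-down room air replicate 3, 236 without knock-down smoke replicate 4 and 0 in a fit of the 4 groups alone (limma; 2495 at unadjusted p under 0.05). It was 669 with the Xist covariate and 38 with centred arrays.

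Smoke for 8 months raised 4 genes and lowered 1 in septa. Ctsk, the collagen-degrading protease cathepsin K, rose from 4.91 ± 0.54 to 10.73 ± 1.60 (SD, n = 5 each; limma adjusted p = 0.000224). Serpina1e, of the alpha-1-antitrypsin family, rose by 4.51 ± 0.71 (SE, limma adjusted p = 0.00276) and Ly6i, a myeloid surface protein, by 4.10 ± 0.70 (SE, limma adjusted p = 0.00872). AU015791, outside the naming rule and chosen after its values were seen, rose by 3.02 (limma adjusted p = 0.0244). Rsph3a, of the ciliary radial spoke, fell by 3.30 ± 0.61 (SE, limma adjusted p = 0.0217), with 1 of 2 probes in that direction. The named genes moved that way on 5 of 5 smoke arrays. The room air means of Ctsk, and of Saa3 and Chil4 below, and the smoke mean of Rsph3a lay under the percentile of 40. Without the low-correlation arrays, which lie in other groups and enter only the shared spread, 92 genes rose and 48 fell. Among those that rose were the acute phase protein Saa3 by 5.81, the neutrophil chemokine Cxcl1 by 4.15, Gpnmb by 4.12, the chitinase-like Chil4 by 3.93 and Ch25h, which makes a hydroxycholesterol, by 3.91. Spp1, osteopontin, rose by 3.77, Trem2, a lipid-sensing receptor of macrophages, by 3.70, Chil3 by 3.45, Lcn2, an iron-binding neutrophil protein, by 3.17 and the metallothioneins Mt2 and Mt1 by 3.74 and 3.48. Cd8a, of cytotoxic T cells, fell by 2.83. With all arrays these genes had limma adjusted p from 0.06 to 0.458.

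As groups, smoke-exposed and lipid-loaded macrophage genes rose for 1 of 20 (11 adjusted over the list alone), with a median of 1.87 in these septa. Camera gave an adjusted p of 6.21e-14, but an adjusted p of 0.118 with an estimated correlation, and 0.00401 as that p without the low-correlation arrays. Alveolar macrophage genes rose for 1 of 20 (8 adjusted over the list alone), with a median of 1.91 (camera adjusted p = 6.21e-14, but adjusted p = 0.0855 with an estimated correlation). The list of inflammatory cytokines and chemokines had a median of 1.16 and 6 of 28 up when adjusted over the list alone. Its camera adjusted p was 2.01e-07, and its adjusted p was 0.02 with an estimated correlation. Transitional alveolar epithelium genes had a median of 1.44 (camera adjusted p = 1.01e-05, but adjusted p = 0.301 with an estimated correlation). Matrix proteases and inhibitors rose for 1 of 27 (4 adjusted over the list alone; camera adjusted p = 4.11e-05, but adjusted p = 0.118 with an estimated correlation). The AHR and NRF2 xenobiotic response had a median of 0.57 and 2 of 26 up when adjusted over the list alone (camera adjusted p = 0.000356, but adjusted p = 0.118 with an estimated correlation). T and NK cell genes had a median of -0.28. The 5 calls became 2 without room air control replicate 2, 24 without smoke control replicate 2 and 607 with array weights.

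**Figure D3:**
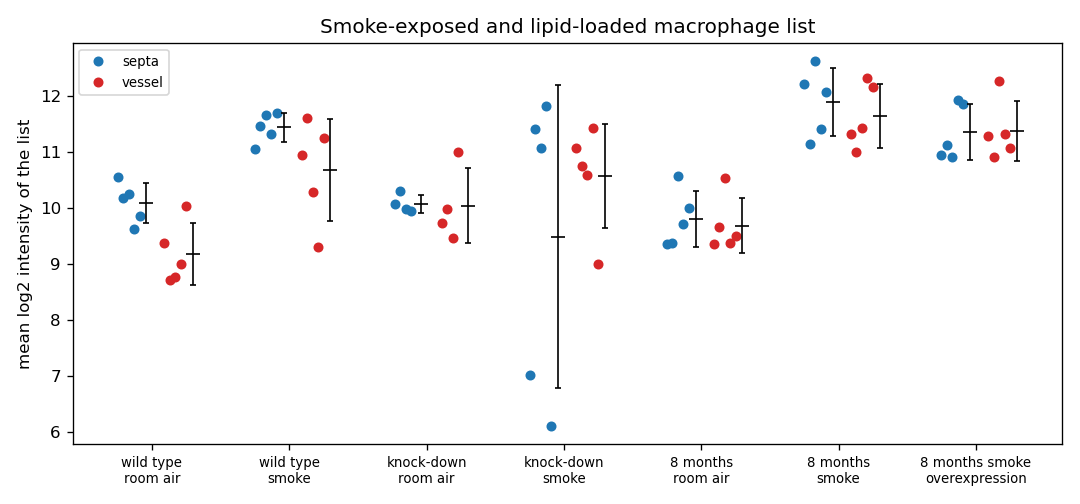
Mean log2 signal of the list of smoke-exposed and lipid-loaded macrophages on each array, by group, with the mean and standard deviation beside the points of each group and septa and vessel in separate colours. In septa the list had a median change of 1.87 after 8 months of smoke against room air, with 1 of 20 genes past the threshold (camera adjusted p = 6.21e-14, but adjusted p = 0.118 with an estimated correlation), and knock-down smoke septa replicate 5 lies at 6.11.

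In vessel, 8 months of smoke gave no gene past the threshold (limma; 0 of 22517, 798 at unadjusted p under 0.05). Lcn2 was closest, at 2.85 ± 0.50 (SE, n = 5 per group; limma adjusted p = 0.0678), and rose without the low-correlation array (limma adjusted p = 0.00498). Fut10, H2-Eb1 of antigen presentation, Acp5, the tartrate-resistant phosphatase of macrophages and osteoclasts, and Lilra5 lay between 2.97 and 3.78 (limma adjusted p = 0.298 each), with Fut10 and Lilra5 under the percentile of 40 in room air. With array weights 9 genes passed, in a fit of these groups alone 2, and with centred arrays 1. Smoke-exposed macrophage genes rose as a list, with a median of 1.60 and 12 of 20 up when adjusted over the list alone (camera adjusted p = 3.44e-23, and adjusted p = 0.00171 with an estimated correlation). Alveolar macrophage genes had a median of 1.25 and 6 of 20 up when adjusted over the list alone (camera adjusted p = 3.25e-09, and adjusted p = 0.0346 with an estimated correlation). Transitional epithelium genes had a median of 0.78 and 3 of 17 up when adjusted over the list alone (camera adjusted p = 2.35e-06, and adjusted p = 0.0346 with an estimated correlation). Matrix proteases and inhibitors had a median of 0.22 and 5 of 27 up when adjusted over the list alone (camera adjusted p = 0.000297, and adjusted p = 0.0473 with an estimated correlation). Beside these, pulmonary vein cardiomyocyte genes had 21 of 22 negative changes and a median of -1.65 (camera adjusted p = 3.25e-09, but adjusted p = 0.186 with an estimated correlation). Vascular smooth muscle genes had a median of -0.49 (camera adjusted p = 0.000208, but adjusted p = 0.129 with an estimated correlation).

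Against smoke controls, the arrays labelled overexpression had no gene past the threshold in septa (limma; 0 of 21752, 497 at unadjusted p under 0.05) or vessel (limma; 0 of 22517, 577 at unadjusted p under 0.05). Chance alone gives about 1087.6 and 1125.85 at that level. In septa the smallest p values were those of AU015791 at -2.48 ± 0.57, Serpina3c at 2.62 ± 0.66, Ctsk at -3.12 ± 0.79, Snhg12 at -2.83 ± 0.73 and Mcpt8, a basophil protease, at 3.80 ± 1.06 (SE, n = 5 per group; limma adjusted p = 1 each). In vessel they were Asap3 at -4.47 ± 0.81 (SE, limma adjusted p = 0.109), Gm14461 at 2.33 ± 0.55, Arnt2 at -3.39 ± 0.81, Cd163l1 at -4.19 ± 1.00 and Stfa2l1 at 3.23 ± 0.78 (SE, limma adjusted p = 0.93 each). Without the low-correlation array Asap3 fell by 4.47 (limma adjusted p = 0.0446). In septa 0 genes passed without the low-correlation arrays (limma, 1674 at unadjusted p under 0.05). The lower means of Snhg12, Mcpt8, Asap3, Gm14461, Arnt2 and Stfa2l1 lay under the percentile of 40. Alveolar macrophage genes in septa had a median of -0.80 and 17 of 20 negative changes (camera adjusted p = 0.000186, but adjusted p = 0.923 with an estimated correlation). Interferon-stimulated genes in septa had a median of -0.37 (camera adjusted p = 0.022, but adjusted p = 0.923 with an estimated correlation). Elastic fibre genes in vessel had a median of -0.50 (camera adjusted p = 0.00354, but adjusted p = 0.439 with an estimated correlation). Across genes, which are not independent replicates, this effect correlated with that of 8 months of smoke at -0.65 in septa and -0.38 in vessel. Simulated values with no effect and each group's own spread gave -0.64 and -0.50, since the smoke controls enter both effects. With those controls split the correlations were -0.15 and 0.06.

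Against room air, the arrays labelled overexpression after smoke had Ly6i higher in septa, by 4.41 ± 0.70 (SE, n = 5 per group; limma adjusted p = 0.00662; 5 of 5 arrays), the only gene to pass there. Chil3 was at 3.97 ± 0.87, Orm1 at 3.42 ± 0.76, Serpina1e at 3.20 ± 0.71 and Stfa2l1 at 3.69 ± 0.82 (SE, limma adjusted p = 0.298 each), with the room air mean of Orm1 under the percentile of 40. When the low-correlation arrays were left out, 21 genes rose, among them Lcn2 by 3.98 (limma adjusted p = 9.82e-07), Cxcl5 by 4.56, Chil3 by 3.97 and Spp1 by 3.68. Inflammatory cytokines had a median of 1.43 and 5 of 28 up when adjusted over the list alone (camera adjusted p = 1.66e-13, and adjusted p = 0.000384 with an estimated correlation). In vessel 6 genes rose and 3 fell. Lcn2 rose from 12.60 ± 0.25 to 15.87 ± 0.09 (SD, n = 5 each; limma adjusted p = 0.00636). Cxcl5 rose by 5.99 ± 1.17, Tnfsf9, a T cell costimulator, by 4.51 ± 0.85, the cystatin Stfa2 by 4.12 ± 0.82 and the serine protease inhibitor Serpina3i by 3.37 ± 0.63. Cd163l1, a scavenger receptor, fell by 5.26 ± 1.00 and Tuba8, an alpha-tubulin, fell by 3.63 ± 0.72 (SE, limma adjusted p from 0.0403 to 0.0458). Lcn2 and Chil3 on overexpression arrays read close to the highest value deposited, and the lower means of Cxcl5, Tnfsf9, Stfa2 and Tuba8 in vessel lay under the percentile of 40. Leaving out any single array of these groups lowered the vessel count of 9, to between 1 and 3, and moved the septa count between 0 (without overexpression replicate 3) and 1.

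Lists in that vessel comparison moved in both directions. Smoke-exposed macrophage genes had a median of 1.82 and 11 of 20 up when adjusted over the list alone (camera adjusted p = 2.11e-16, and adjusted p = 0.0139 with an estimated correlation). Neutrophil genes rose for 1 of 20 (3 adjusted over the list alone; camera adjusted p = 2.55e-06, and adjusted p = 0.0202 with an estimated correlation). Circadian clock genes had a median of 0.95 and 2 of 17 up when adjusted over the list alone (camera adjusted p = 6.97e-06, and adjusted p = 0.0202 with an estimated correlation). Vascular smooth muscle genes had 21 of 21 negative changes and a median of -0.79 (camera adjusted p = 3.22e-08, and adjusted p = 0.0202 with an estimated correlation). Elastic fibre genes had a median of -0.74 (camera adjusted p = 9.41e-06, and adjusted p = 0.0202 with an estimated correlation).

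The smoke effect at 8 months was set against that at 3 months by a test of the difference. In septa Serpina1e differed, by 6.07 ± 1.01 (SE, n = 5 per group; limma adjusted p = 0.014), the only gene to pass. No gene did with the mean of all probes (limma; 0, 1728 at unadjusted p under 0.05) or without room air control replicate 3 of 8 months. Serpina1c differed by 5.99 ± 1.36 and Serpina1b by 5.15 ± 1.19 (SE, limma adjusted p = 0.36 each), and Serpina1c passed without the low-correlation arrays (limma adjusted p = 0.0466). In vessel no gene passed (limma; 0 of 22517, 1542 at unadjusted p under 0.05), with Rnase6 at -5.71 ± 1.10 and the mast cell protease Mcpt4 at 7.38 ± 1.63. The groups of 8 months had their own controls and later treatment, so exposure time cannot be parted from these.

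Effects in septa were set against those in vessel in the same way. For knock-down under smoke 359 genes differed upward and 240 downward, among them Susd1 at 5.47 ± 1.05, the orphan receptor Nr4a3 at 4.78 ± 1.04, Plekhd1 at -5.80 ± 1.17 and Clock, the circadian activator, at -5.23 ± 1.14 (SE, n = 5 per group; limma adjusted p from 0.00769 to 0.0157). That fit took septa and vessel arrays as independent, and with the replicate number as a block 1087 genes passed. Some of these blocks pair arrays of differing Xist class, so they do not all join arrays of 1 animal. When the low-correlation arrays were left out, 6 genes passed, 3 of them shared. No gene passed for smoke at 3 months (limma; 0 of 24150, 988 at unadjusted p under 0.05), knock-down in room air (limma; 0, 1007 unadjusted), smoke at 8 months (limma; 0, 828 unadjusted, and 1 gene with the block) or overexpression after smoke (limma; 0, 489 unadjusted). Leaving out wild-type smoke vessel replicate 4 took the 599 calls to 10, and leaving out knock-down smoke septa replicate 2 took them to 2743.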

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

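The tests of the low-correlation arrays and of misplaced values, and the simulation with each group's own spread, were chosen only after the results they concern were seen. Values of an array were compared with the other arrays of its group in 56 tests, of which 6 stood apart, where chance gives about 1 in 20.

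Knock-down smoke septa replicates 1 and 5 lay far from their group in the 628 genes called for knock-down under smoke. Those genes and their signs were chosen with these arrays in the fit. Large differences on them are therefore partly built in and are not separate evidence. Per array, the median difference from wild-type smoke, signed by the called direction, was 6.10 in replicate 1 and 6.23 in replicate 5, against 0.24, 2.14 and 0.45 in replicates 2, 3 and 4. Values set against the wrong features is an explanation that the tables go with for replicate 5: its correlation with the median septa profile was 0.00102 in place and 0.336 when moved by 328 features, and 67 of 68 arrays matched best unmoved. At its best 0.336 still lay below the next lowest array, replicate 1 at 0.364, so the move did not restore the profile. Without both arrays 0 genes passed (limma, 1036 at unadjusted p under 0.05). Of the 9 other pairs of knock-down smoke arrays 2 also gave 0, but each of those held 1 of these arrays together with replicate 3. Leaving out pairs of the other arrays gave 7737, 7759 and 8951 genes. The calls therefore needed at least 1 of these arrays. Whether these arrays alone account for the calls, without replicate 3, cannot be told apart. An effect of the knock-down was not tested by the change left in the remaining arrays, which was 31.2 percent (SE 19.3) of the median signed change of the called genes, from 3.12 to 0.97. The genes and their signs came from a fit that held these same arrays, so some change would be left with no effect.

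In vessel, 17 of the genes raised by smoke in wild type were also raised on the arrays labelled knock-down in room air, both against the same wild-type room air arrays. The covariance of the changes over all genes was 0.672, against 0.463 in simulated values with no effect, shared controls and each group's own spread. With the controls split between the comparisons it was 0.212 (0.176 to 0.262 over 10 splits), which is 31.6 percent of the unsplit value. The shared control arrays may therefore account for part of the overlap. The covariance stayed above 0 in all 10 splits, so an effect common to smoke and knock-down stays open. Splitting does not remove a difference that all wild-type room air arrays share, so the splits cannot part that from such an effect.

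Smoke-exposed macrophage genes had a median change of 1.87 after 8 months of smoke in septa, with 1 of 20 past the threshold (camera adjusted p = 6.21e-14, but adjusted p = 0.118 with an estimated correlation). Over the 16 genes found in that list alone the mean change was 1.87, and over the 16 found in the alveolar macrophage list alone 1.80. Per array the difference between these means was 0.064 larger under smoke (exact two-sided permutation p = 0.81, n = 5 per group), so more macrophages in the pieces cannot be told apart from a changed state of them at this number of arrays. A lower share of the rest of the piece would raise every other leukocyte list. The median of the T and NK cell list was -0.28 (SE 0.256), below 0 by barely more than its SE, the mark set beforehand. That SE is taken over genes of the list, which are not independent, and not over arrays, so it cannot decide on this explanation. The other lists stood at 0.21 (SE 0.286) for interstitial macrophages, 0.86 (SE 0.247) for neutrophils and -0.20 (SE 0.248) for B cells.

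Fgf10 stood apart from its group in knock-down room air vessel replicate 4, at 6.78 with the nearest at 5.23, and in wild-type room air vessel replicate 3, at 8.54 with the nearest at 5.02. The median correlation stood apart for smoke control septa replicate 4 of 8 months, at 0.725 with the nearest at 0.892, and for knock-down smoke vessel replicate 5, at 0.456 with the nearest at 0.755. The mean of the smoke-exposed macrophage list was 10.5 in room air control vessel replicate 3, with the nearest at 9.67. The mean of the clock list was 7.72 in wild-type room air vessel replicate 4, with the nearest at 8.01. Effects differed by a test of the difference for 1 gene between 8 and 3 months of smoke in septa (Serpina1e, 6.07 ± 1.01, SE; limma adjusted p = 0.014). They differed for 5 genes between the smoke effects of knock-down and wild type in vessel, and for 599 genes between septa and vessel for knock-down under smoke. The second Fgf10 probe, not the one that stood for Fgf10, was higher on arrays labelled overexpression than on smoke controls by 1.58 in septa (exact two-sided permutation p = 0.151) and 2.22 in vessel (exact two-sided permutation p = 0.119), n = 5 per group. Limma gave unadjusted p of 0.0926 and 0.0116 for these.

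For each comparison 100 splits of the same arrays into groups of the same sizes were fitted, the real one included. The real split alone gave as many genes for septa against vessel (4782, highest other 42), so chance can be excluded for that count. It also did so for smoke of 8 months in septa (5, highest other 1) and overexpression against room air in vessel (9, highest other 1). Standing alone among 100 splits is a low bar over 24 comparisons. Leaving out 1 array took these 2 counts as low as 2 and 1, so chance is not excluded for them. Counts of 1 gene met the same bar for smoke in wild-type septa (the real split alone, highest other 0), 8 against 3 months in septa (the real split alone, highest other 0) and overexpression against room air in septa (2 splits, highest other 1). With 1 gene each among 24 comparisons this is a weak bar, and the count for wild-type septa was 0 with centred arrays and with the mean of all probes (limma; 806 and 881 at unadjusted p under 0.05), so chance is left open for these. For knock-down in room air in vessel 4 did (72, highest other 325), and for smoke in the knock-down in vessel 4 did (41, highest other 431), but with other splits at several times these counts a structure of the arrays stays open as their source. Chance cannot be excluded for knock-down under smoke in septa, with 17 splits (628, highest other 2975), or in vessel, with 5 splits (1210, highest other 2136). It cannot be excluded for smoke in wild-type vessel with 11 splits (32, highest other 1682), the interaction in vessel with 10 (5, highest other 4504) and septa minus vessel for knock-down under smoke with 14 (599, highest other 4881). The source of splits with more genes than the real one was not tested. For a difference of effects the splits moved arrays among all of its groups, septa and vessel included where both entered. Differences between those groups can then raise the counts, so these splits cannot decide on chance there. For the counts of 0 all 100 splits gave as many, which excludes nothing; their highest other counts were 6163 for smoke in the knock-down in septa, 4032, 64, 39 and 15 for septa minus vessel (smoke of 3 months, knock-down in room air, smoke of 8 months, overexpression), 981 for 8 against 3 months in vessel, and 0 to 2 for the others.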

How the results depend on the processing

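The fits without the low-correlation arrays, with the Xist covariate and with both were chosen only after the results were seen, as was leaving out single arrays for septa against vessel and for differences of effects. Counts are genes past the threshold, and a count is called moved when it differs from that of all arrays by over 1.5 times. With no filter 25 results were the same and 1 moved, with the mean of all probes 17 and 7, with centred arrays 18 and 6, with the replicate block 16 and 8. With the Xist covariate it was 14 and 10, without the low-correlation arrays 7 and 17, with both 7 and 17, with array weights 0 and 17, and in fits of the compared groups alone 6 and 10. Leaving out 1 array gave 261 the same and 119 moved. Quantile normalisation was not run, since the values held it already. Except where a value below shows it, the cause was not tested. For comparisons that hold none of the low-correlation arrays, leaving those out changes only the shared spread, not the group means.

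With no filter knock-down under smoke in septa had 0 genes. With the mean of all probes, smoke in wild-type septa had 0, knock-down under smoke in septa 0, overexpression in septa 1, 8 minus 3 months in septa 0, smoke in wild-type vessel 1, the interaction in vessel 8 and septa minus vessel for knock-down under smoke 388. With each array centred on its median, smoke in wild-type septa had 0, knock-down under smoke in septa 0, smoke in the knock-down in septa 1, knock-down under smoke in vessel 763, the interaction in vessel 38 and smoke of 8 months in vessel 1. With the replicate block, smoke of 8 months in septa had 12, 8 minus 3 months in septa 2, smoke in wild-type vessel 3, knock-down in room air in vessel 32, smoke in the knock-down in vessel 17, overexpression against room air in vessel 4, septa minus vessel for knock-down under smoke 1087 and for smoke of 8 months 1.

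Without the low-correlation arrays, septa had 11 genes for smoke in wild type, 0 for knock-down under smoke, 2 for smoke in the knock-down, 140 for smoke of 8 months, 21 for overexpression against room air and 5 for 8 minus 3 months. Vessel had 135 for smoke in wild type, 210 for knock-down in room air, 22 for smoke in the knock-down, 16 for the interaction, 1 for smoke of 8 months and 1 for overexpression. Septa against vessel had 7835, and septa minus vessel had 1 for smoke in wild type, 5 for knock-down in room air, 6 for knock-down under smoke and 1 for smoke of 8 months. The test of these lists turned direction, with the medians below, but apart from the 1 list with a p value below no call was made, at camera adjusted p of 0.193 to 0.993. For knock-down under smoke in septa they were transitional epithelium -0.018, smoke-exposed macrophages -0.082, neutrophils -0.065, senescence and p53 targets 0.13, ribosomal proteins 0.20 and unfolded protein response -0.015. For smoke in the knock-down in septa they were alveolar type 2 cells -0.033, transitional epithelium 0.17, complement and coagulation -0.23, oxidative phosphorylation -0.026, ribosomal proteins -0.086 and unfolded protein response 0.40. For the interaction in septa they were smoke-exposed macrophages -0.019 and ribosomal proteins 0.27 (camera adjusted p = 0.0139). Medians with a minus sign here differ in sign from their list's test, which turned upward.

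With the Xist covariate, septa had 2 genes for smoke in wild type, 4134 for knock-down under smoke, 3325 for smoke in the knock-down, 10 for the interaction and 2 for 8 minus 3 months. In knock-down smoke septa the arrays without high Xist signal were the low-correlation arrays, so the covariate cannot be told apart from them there. Vessel had 139 for smoke in wild type, 1850 for knock-down under smoke, 669 for the interaction and 1 for smoke of 8 months, and septa minus vessel had 1 for smoke of 8 months. With the covariate and without the low-correlation arrays, septa had 16 for smoke in wild type, 0 for knock-down under smoke, 120 for smoke of 8 months, 17 for overexpression against room air and 8 for 8 minus 3 months. Vessel then had 385 for smoke in wild type, 311 for knock-down in room air, 1984 for knock-down under smoke, 13 for smoke in the knock-down, 322 for the interaction, 1 for smoke of 8 months and 15 for overexpression against room air. Septa against vessel had 7871, and septa minus vessel had 1 for smoke in wild type, 4 for knock-down in room air, 6 for knock-down under smoke and 1 for smoke of 8 months.

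With array weights, septa had 21 genes for smoke in wild type, 23 for knock-down in room air, 0 for knock-down under smoke, 33 for smoke in the knock-down, 3 for the interaction, 607 for smoke of 8 months, 1 for overexpression and 77 for overexpression against room air. Vessel had 165 for smoke in wild type, 136 for knock-down in room air, 4406 for knock-down under smoke, 77 for smoke in the knock-down, 47 for the interaction, 9 for smoke of 8 months, 3 for overexpression and 49 for overexpression against room air. Septa against vessel had 10481. In fits of the compared groups alone, septa had 4 for smoke in wild type, 0 for knock-down under smoke and 15 for overexpression against room air. Vessel had 0 for smoke in wild type, 28 for knock-down in room air, 0 for knock-down under smoke, 0 for smoke in the knock-down, 0 for the interaction, 2 for smoke of 8 months and 5 for overexpression against room air; these fits hold fewer arrays. Counting the sample of conflicting labels as knock-down left 0 genes for smoke in wild-type septa and 0 for knock-down under smoke in septa. In the wild-type room air groups of 3 months alone, 460 genes passed for septa against vessel, with fewer arrays. For knock-down under smoke in septa the second Fgf10 probe turned direction, at 1.34. The dimmest read 0.53, but lay above the percentile of 40 on 1 of 5 knock-down and 0 of 5 wild-type arrays, which gives no direction. With the smoke controls split, the correlation across genes of the overexpression effect with the 8-month smoke effect was -0.146 in septa and 0.0567 in vessel.

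Leaving out 1 array at a time gave these ranges in septa: smoke in wild type 0 to 2, knock-down in room air 0 to 0, knock-down under smoke 0 (without knock-down smoke replicate 1) to 5076 (without replicate 2), smoke in the knock-down 0 to 4864 and the interaction 0 to 556. Also in septa they were 2 to 24 for smoke of 8 months, 0 to 1 for overexpression, 0 to 1 for overexpression against room air and 0 to 2 for 8 minus 3 months. In vessel they were 2 to 264 for smoke in wild type, 4 to 215 for knock-down in room air, 308 to 1773 for knock-down under smoke, 0 to 295 for smoke in the knock-down, 0 to 236 for the interaction, 0 to 1 for smoke of 8 months, 0 to 1 for overexpression, 1 to 3 for overexpression against room air and 0 to 2 for 8 minus 3 months. Septa against vessel ranged from 4391 to 6102. Septa minus vessel ranged from 10 to 2743 for knock-down under smoke, 0 to 2 for smoke in wild type, 0 to 0 for knock-down in room air, 0 to 1 for smoke of 8 months and 0 to 0 for overexpression.

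Signal over background limits what can be said of Fgf10. Its brightest probe lay above the percentile of 40 on 2 of 5 knock-down smoke arrays in septa and on 2 of 5 in vessel. In room air vessel it did so on 1 of 5 wild-type and 1 of 4 knock-down arrays, and genes above it on fewer than 4 arrays were not tested.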

Other observations

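The relation of the knock-down effect to the smoke effect and the matching by Xist signal were tests chosen only after results were seen. Across genes, which are not independent replicates, the effect of the knock-down in room air correlated with that of 3 months of smoke at 0.665 in septa and 0.617 in vessel. Simulated values with no effect and each group's own spread gave 0.672 and 0.682, since the wild-type room air arrays enter both effects, and with those arrays split the correlations were 0.135 and 0.144.

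Of the gene lists, 7 had no camera call in any comparison. Their smallest camera adjusted p was 0.0693 for pericytes, 0.0501 for nitric oxide and superoxide enzymes, 0.0546 for integrated and mitochondrial stress, 0.0912 for platelets, 0.422 for mesothelium, 0.13 for adipocytes and 0.13 for sex-linked genes. The fry test called 28 lists for septa against vessel, and in septa 25 for smoke in the knock-down and 21 for knock-down under smoke. Elsewhere fry called 0 to 6. For 3 months of smoke in wild-type septa fry called 0, where camera called 7 up and 2 down. For 8 months in septa fry called 2, where camera called 10 up.

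Septa and vessel arrays with the same group and replicate number were in the same class of Xist signal in 28 of 34 cases, where permuted numbers within groups give 19.7 on average (exact one-sided permutation p = 0.00516). The number of arrays with high Xist was equal in septa and vessel in 7 of 7 groups. In 7 of 34 cases the deviations of such a pair from their group means correlated over 0.1 across genes, within a range of -0.24 to 0.38, and since not all did, the numbers were not used as pairs. Shared animals stay open, and the fit of septa against vessel, which took its arrays as independent, had 4782 genes against 5277 with the number as a block.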
